A study of Mus musculus with 51 samples.

How the data were processed

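Total RNA was measured on 51 Affymetrix oligonucleotide arrays, 1 biotin-labelled sample per array, from 4 blood-forming cell populations sorted by flow cytometry out of mouse bone marrow. Cells went straight into RNA extraction buffer, and a 2-cycle amplification preceded hybridisation, per the labels' protocols. Sample titles set the groups: wild type or Mll-AF9 knock-in, each for granulocyte-macrophage progenitors (GMP), common myeloid progenitors (CMP), common lymphoid progenitors (CLP) and haematopoietic stem cells (HSC). The source name of 8 samples titled CLP, wild type CLP replicate 1 and all 7 Mll-AF9 CLP replicates, was that of CMP, and the title was followed. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these samples, which may be partly technical. Age, sex and zygosity of the mice are not given in the sources used here.

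The authors deposited 1 intensity per probe set and array, summarised by RMA (background correction, quantile normalisation and median polish), per the submitters' processing notes. The RMA version, and whether all arrays were normalised together, are not given in the sources used here. The deposited intensities were on a linear scale, as their range and near-equal quantiles showed, and log2 was taken before any other step. CMP values carried more decimals than the others, so CMP arrays may have been processed apart, and each genotype comparison was made within 1 population. Counts of genes between CMP and other populations, the differences of the genotype effect with CMP and the signatures taken against CMP depend on this. No depth exists for arrays, and the number of arrays limits the precision. Between 55.5% and 63.2% of the genes of a replicate lay above the background level defined below.

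Most CMP replicates were hybridised in 2 runs. The runs of a replicate were averaged on the log2 scale for 8 replicates, which left 43 replicates. The standard deviation over genes between runs of 1 replicate was 0.29 to 0.51, against 0.24 to 0.44 between averaged CMP replicates of 1 group. In a fit of the repeat runs with the replicate as a random effect (correlation 0.261), 2208 genes differed between the runs, and averaging keeps 1 value per replicate.

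Of 45101 probe sets, 64 were controls and were left out. Of the others, 34945 had 1 gene in the platform annotation and 10092 had several or none. Symbols were updated through the gene identifier for 34754 probe sets, controls included, from the GRCm38.p6 gene table, which was used for names and for gene order only. Each gene was represented by the probe set with the highest mean over all replicates, which gave 18193 genes. The background level was 4.46 on the log2 scale, the 95th percentile of the mean values of 112 olfactory, vomeronasal and taste receptor and keratin-associated protein genes. Lower bounds of folds raise each replicate of the dimmer group to at least that level, where the mean of that group lies below it.

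Genotypes were compared within each population with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without a block or covariate. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over 18193 genes. Standard errors (SE) are limma's moderated ones, and every difference is Mll-AF9 minus wild type on the log2 scale. Differences of the genotype effect between populations were tested as contrasts of contrasts in 1 limma model of all 8 group means. Gene lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 19 lists of a comparison, and with fry. Adjusted p-values of lists are camera's with the preset correlation unless an estimated correlation is named.

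Before the data were examined, the design, the alternatives, the gene lists and the rule for named genes were fixed. The lists were the HoxA cluster, the HoxB cluster, MLL-fusion target genes outside the Hox clusters, haematopoietic stem cell, neutrophil and primary granule, monocyte and macrophage, erythroid and megakaryocyte, lymphoid progenitor, mature B cell, mature T and NK cell, stroma and endothelium, mast cell and basophil, cell cycle, interferon response, immediate-early and heat-shock stress, p53 response, MYC and ribosome biogenesis, MHC class II and CDK inhibitors. Sex-linked genes and the targeted locus made up the remaining lists and were described without a list test. Some genes stood on more than 1 list, such as Mecom and Meis1 on both the MLL-fusion target and the stem cell list and Gzmb on both the T and NK cell and the mast cell list.

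Named genes were, per comparison, the 10 higher and 10 lower genes with the largest absolute difference among called genes whose brighter group lay above background, with clone names passed over. The rule added up to 15 genes called the same way in all 4 populations, the 5 largest differences per pair of populations, and per list up to 4 called members or, with none called, the 2 with the smallest p. Hoxa and Hoxb genes, Meis1, Mecom, Kmt2a and Mllt3 could always be named. Outside this rule, and chosen after values were seen, are the markers Mpo, Klf1, Il7r and Dntt, the Cd3 genes, a clone gene in HSC and some genes given for a population or signature other than the one that named them. Wild-type signatures were up to 200 genes with the highest moderated t among those called with a log2 difference over 1 between wild-type populations, taken from libraries other than those of the tested comparison. They were tested with camera and adjusted over the signature tests.

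Each step was tested on simulated data with the real genes' levels and spread and known changes, in 5 simulations over 18193 genes that together held 250 changed genes at each of 4 sizes. At a 4-fold change the genotype comparison recovered 98.4% of changed genes in GMP, 100% in CMP, 98.4% in CLP and 94% in HSC. At a 2-fold change it recovered 72% in GMP, 93.6% in CMP, 67.6% in CLP and 52% in HSC. False calls per simulation averaged 8.6 in GMP, 12.4 in CMP, 7.6 in CLP and 6.4 in HSC. False calls of the test of differences between populations averaged 50.6 per simulation for CLP against HSC, 15.4 for GMP against HSC, 12.2 for GMP against CLP, 11 for CMP against HSC, 4.8 for CMP against CLP and 3.2 for GMP against CMP. A fit on the 4 groups of a pair alone made, in the same order, 8.4, 6.8, 2.8, 7.4, 2.4 and 13.2. With no change simulated, a test chosen after seeing the data, the model of 8 groups called 4.65, 1.3, 0.65, 0.2, 0.05 and 0.05 genes on average over 20 simulations, and at most 17, 8, 5, 2, 1 and 1. The list test recovered the raised list in 5 of 5 simulations in each population and called no other. Genes were drawn independently in all these simulations. In the data, members of a list can be correlated, with an estimated correlation of 0.766 for neutrophil genes in CMP. The simulations therefore do not show how many false list calls the preset correlation makes on such lists. Other splits of the real replicates, described below, called a median of 1 list in GMP, 2 in CMP, 4 in CLP and 3 in HSC.

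Alternatives were 1 model over 8 groups, other empirical Bayes priors, array weights, filters on dim genes, repeated quantile normalisation, median centring, other probe set choices, each replicate left out, the replicate number as a block, the 3' minus 5' difference of Actb and Gapdh control probe sets as a covariate, and other treatments of the CMP runs. Signatures were also taken against another wild-type population or with 100 genes. A covariate for the level of Y-linked genes, and a fit without replicates with a high 3' minus 5' difference, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.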

Results

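The series compared gene expression in 4 populations of blood-forming cells sorted from the bone marrow of wild-type mice and of Mll-AF9 knock-in mice. Mll-AF9 is a leukaemia fusion of the histone methyltransferase gene Mll (Kmt2a) with Af9 (Mllt3). GMP give rise to granulocytes and macrophages, CMP to myeloid and erythroid cells, CLP to lymphocytes, and HSC to every blood lineage. The stated question was which genes differ between Mll-AF9 cells of a population and their wild-type counterparts. After repeat runs were averaged there were 5 wild-type and 4 Mll-AF9 replicates of GMP, 5 and 4 of CMP, 8 and 7 of CLP, and 5 and 5 of HSC. Values are log2 RMA intensities, and a level below 4.46 was taken as background. Where the dimmer group of a called gene had its mean below background, its log2 difference rests on background values. For genes named by the rule whose brighter group lay above background, a lower bound of the fold is then given. This bound can lie far below the fitted difference.

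Marker levels were compared with the titles. Mpo, the granule myeloperoxidase, had a mean of 13.70 ± 0.13 (SD, n = 5) in wild-type GMP and 10.86 ± 0.45 (SD, n = 5) in wild-type CMP, with 11.79 ± 1.02 (SD, n = 8) in wild-type CLP. Klf1, an erythroid transcription factor, stood at 11.38 ± 0.22 (SD, n = 5) in wild-type CMP and 5.75 ± 0.75 (SD, n = 5) in wild-type GMP. Il7r, the interleukin-7 receptor chain that CLP carry, stood at 9.54 ± 1.23 (SD, n = 8) in wild-type CLP, 9.49 ± 1.36 (SD, n = 7) in Mll-AF9 CLP and 5.05 ± 0.35 (SD, n = 5) in wild-type HSC. The Mll-AF9 CLP samples, whose source name is that of CMP, had Klf1 at 7.79 ± 1.08 (SD, n = 7) against 11.31 ± 0.18 (SD, n = 4) in Mll-AF9 CMP, and so sat with CLP. Kmt2a had differences of −0.45 ± 0.18 (SE) in GMP, −0.55 ± 0.13 in CMP, −0.56 ± 0.23 in CLP and −0.50 ± 0.34 in HSC, and none of these differences was called (limma adjusted p = 0.44, 0.09, 0.47 and 0.82). Mllt3 was not called either, with differences of −0.27, 0.13, −0.03 and 0.45. Where these probe sets lie relative to the fusion point was not analysed here, so they do not check the labels.

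All 20 Mll-AF9 replicates had Xist, the X-inactivation transcript of female cells, between 10.65 and 12.10, and a mean of the Y-linked genes Kdm5d, Eif2s3y and Uty between 2.21 and 2.72. Wild-type groups were mixed. The Y-linked mean lay above 6 in 3 of 5 GMP, 3 of 5 CMP, 6 of 8 CLP and 2 of 5 HSC replicates, so genotype and sex of the mice overlap in every comparison. Ddx3y, the other member of the sex-linked list, was not used here.

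**Figure D1:**
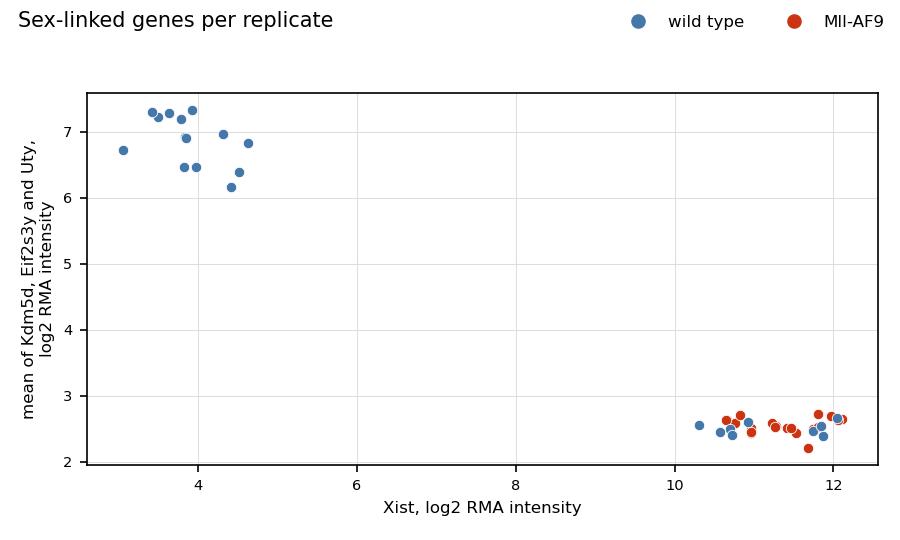
Level of Xist (x axis, log2 RMA intensity) against the mean of Kdm5d, Eif2s3y and Uty (y axis, log2 RMA intensity), 1 point per replicate, wild type in blue and Mll-AF9 in red. All 20 Mll-AF9 replicates sit with Xist at 10.65 or above and Y-linked genes at 2.72 or below, together with part of the wild-type replicates.

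In GMP, Mecom, which encodes the stem cell transcription factor EVI1, rose in Mll-AF9. It went from 4.09 ± 0.57 (SD, n = 5) to 7.37 ± 0.48 (SD, n = 4), a difference of 3.29 ± 0.28 (SE, adjusted p = 0.000111) and at least 7.37-fold. Its other probe sets lay below background. Hoxa9, a homeobox gene of early progenitors, rose by 1.79 ± 0.24 (adjusted p = 0.00242) on its main probe set, while a second one above background differed by −0.10 ± 0.17 (adjusted p = 0.909 over all named probe sets). Its partner Meis1 rose by 1.46 ± 0.18 (adjusted p = 0.00181), and Skida1, a little-studied gene, by 2.03 ± 0.26 (adjusted p = 0.00199). Genes of other kinds rose too, among them Tmem178 (2.42), Bpifc (2.37), the peptide transporter Slc15a2 (2.15), Myl10 (2.15), Fbp1 of gluconeogenesis (1.85), Selp, the adhesion molecule P-selectin (1.72), and the desmosomal Dsp (1.71). The largest fall was in Ptger3, a prostaglandin E2 receptor, by 2.16 ± 0.26 (adjusted p = 0.00181), followed by Basp1 (−1.53), Tmem98 (−1.49), Klk8 (−1.42), Gng11 (−1.26), Syde2 (−1.16), Mmp2 (−1.12), the erythroid and stem cell factor Tal1 (−1.09), Fzd6 (−1.05) and Zfp521 (−1.02). The calls of Fbp1 and Fzd6 were lost in 17 and 13 of 22 alternatives.

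Wild-type means lay below background for Mecom, Skida1 (at least 1.47-fold), Bpifc, Myl10, Dsp and Prdm16, and Mll-AF9 means for Fzd6, Zfp521, Pde5a and Fhl1. In all, limma called 31 genes higher and 18 lower in Mll-AF9 GMP among 18193, of which 28 and 11 had a fitted difference over 2-fold. Of the lists fixed in advance, HoxA rose (mean 0.36, 1 of 9 members called, 3 adjusted over the list alone; adjusted p = 0.00293), but adjusted p = 0.158 with an estimated correlation. Hoxa9 was the called member on the chosen probe sets, while a second Hoxa5 probe set rose by 2.31 ± 0.21 (adjusted p = 0.000295 over all named probe sets). MLL-fusion target genes rose by a mean of 0.38 (adjusted p = 0.000297), with adjusted p = 0.266 with an estimated correlation. Of 16 members Mecom and Meis1 were higher and Zfp521 lower, and 5 were higher and 2 lower adjusted over the list alone. Monocyte and macrophage genes rose by a mean of 0.28 (adjusted p = 0.000188), with adjusted p = 0.284 with an estimated correlation. Mpeg1, which encodes perforin-2 of macrophages, was the called member of 15 (0.96 ± 0.17, adjusted p = 0.0204), and 5 were higher adjusted over the list alone. Erythroid and megakaryocyte genes fell by a mean of −0.24 (adjusted p = 0.016), with adjusted p = 0.284 with an estimated correlation and Tal1 the called member of 19, also adjusted over the list alone. MHC class II genes fell by a mean of −0.42 (adjusted p = 0.0206), with adjusted p = 0.345 with an estimated correlation and 0 of 6 members called over all genes or adjusted over the list alone. The erythroid list no longer passed without Mll-AF9 replicate 1 (−0.20) or 2 (−0.22), nor MHC class II without wild type replicate 1 (−0.32) or 2 (−0.40) or Mll-AF9 replicate 2 (−0.26).

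The stem cell list was not called in GMP, and its members moved apart. Mecom and Meis1 were higher, and Tal1 and Fhl1 (−1.01 ± 0.17, adjusted p = 0.0178) lower, 2 in each direction of 22 over all genes and adjusted over the list alone. Its mean was 0.04 and its median −0.12. Cad, an enzyme of pyrimidine synthesis on the MYC and ribosome biogenesis list, fell by 0.93 ± 0.16 (adjusted p = 0.0197), while that list was not called (mean −0.15, adjusted p = 0.165). The 3' minus 5' control difference, a sign of RNA quality, was highest in wild type GMP replicate 1 (4.70), and without it 92 genes were higher and 51 lower. Without wild type replicate 4 the lower genes numbered 8, without Mll-AF9 replicate 1 they numbered 4, and higher and lower genes numbered 17 and 6 without wild type replicate 5, and 20 and 6, 16 and 4, and 18 and 9 without Mll-AF9 replicates 2, 3 and 4. With the level of Y-linked genes as a covariate, chosen after seeing the data, 11 of the 49 genes were called the same way.

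**Figure D2:**
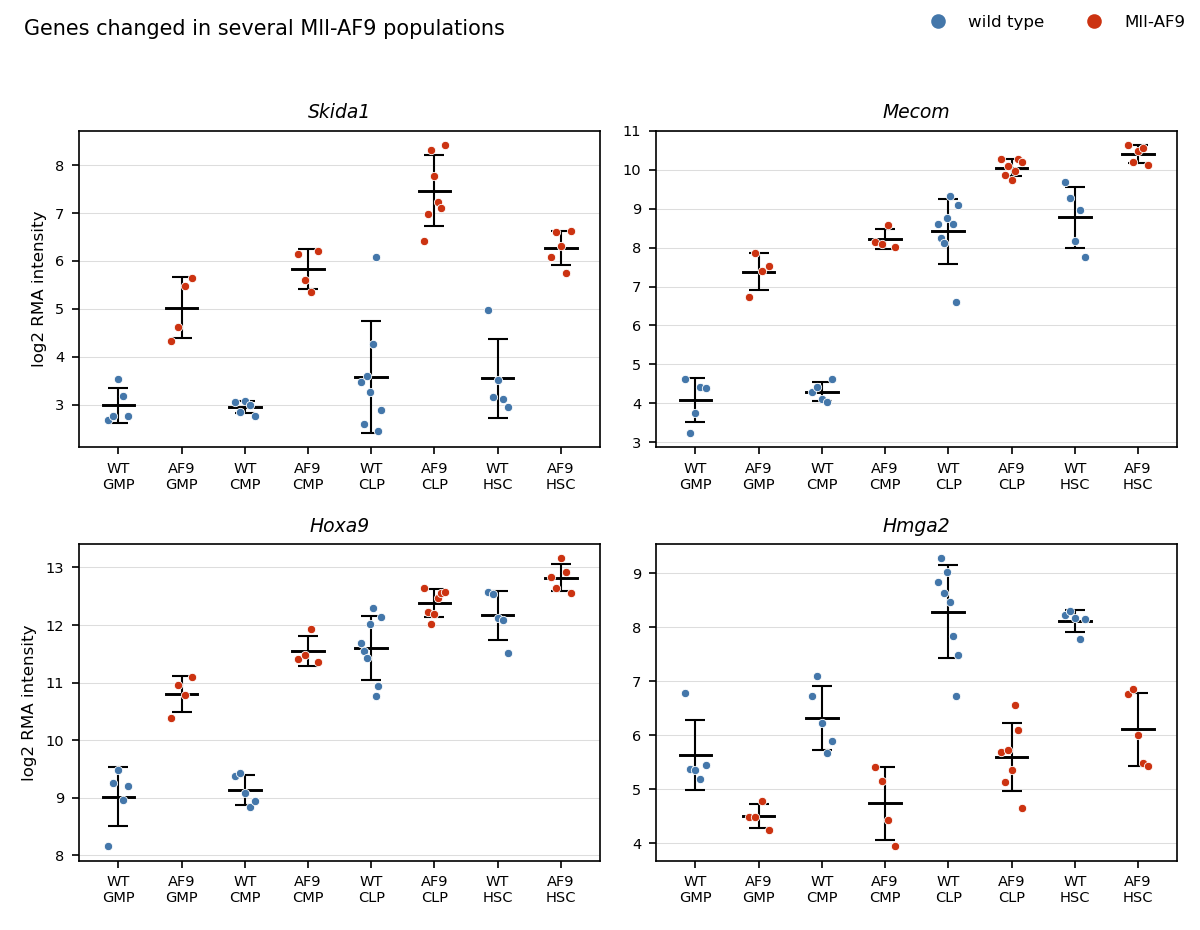
Level of Skida1, Mecom, Hoxa9 and Hmga2 (y axis, log2 RMA intensity) in the 8 groups, 1 point per replicate, with the group mean (bar) and SD (error bar), wild type in blue and Mll-AF9 (AF9) in red. Skida1 was called higher in each population from wild-type means below background (4.46), as was Mecom in GMP and CMP.

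In CMP, Mecom, Skida1 and Hoxa9 rose again. Mecom went from 4.30 ± 0.24 (SD, n = 5) to 8.22 ± 0.25 (SD, n = 4), a difference of 3.92 ± 0.16 (adjusted p = 1.12e-08) and at least 13.2-fold. Skida1 rose by 2.88 ± 0.16 (adjusted p = 6.47e-07), Hoxa9 by 2.41 ± 0.15 (adjusted p = 1.85e-06) and Hoxa10 by 2.22 ± 0.15 (adjusted p = 2.58e-06). The second Hoxa9 probe set rose by 0.85 ± 0.13 (adjusted p = 0.0144 over all named probe sets). Fbp1 (2.43), Il18r1, the interleukin-18 receptor (2.30), Bpifc (2.07), Fgf13 (1.78), Selp (1.70) and the carboxypeptidase Cpd (1.63) rose as well. Ptger3 fell by 2.40 ± 0.20 (adjusted p = 4.15e-05), and Frmd4b (−1.59), Cst7 (−1.59), the chromatin protein gene Hmga2 (−1.58), Stx3 (−1.49), Apoe (−1.42), Slc18b1 (−1.41), the myeloid lectin Clec4d (−1.37), Pde5a (−1.34) and Pgap4 (−1.33) were also lower. The calls of Hmga2, Frmd4b and Clec4d were lost in 17, 14 and 13 of 24 alternatives, and another Pde5a probe set differed by −0.84 without a call. Another Hmga2 probe set fell by 1.69 ± 0.25 (limma adjusted p = 0.0102 over all named probe sets, 0.0789 for the chosen one). A further one above background differed by −0.88 ± 0.23 without a call (adjusted p = 0.231).

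Wild-type means lay below background for Mecom, Skida1 (at least 2.58-fold), Fbp1 (at least 4.86-fold), Hoxa10 (at least 2.10-fold), Il18r1 (at least 3.03-fold) and Bpifc (at least 2.50-fold). They also did for Fgf13 (at least 1.63-fold), Myl10 (at least 1.47-fold), Prdm16 (at least 1.31-fold) and Fcer1a (at least 1.17-fold). Mll-AF9 means lay below it for Frmd4b (at least 1.56-fold), Slc18b1 (at least 2.27-fold) and Eya1 (at least 1.06-fold). limma called 43 genes higher and 34 lower in CMP, 27 and 20 of them with a fitted difference over 2-fold. The HoxA cluster rose as a list (mean 0.92, adjusted p = 9.9e-15) and did so with an estimated correlation (adjusted p = 0.0182). Of 9 measured members 5 rose, also adjusted over the list alone. Beside Hoxa9 and Hoxa10 these were Hoxa5 (1.42), Hoxa7 (0.76) and Hoxa2 (1.11, with both groups below background). A second Hoxa5 probe set rose by 2.88 ± 0.15 (adjusted p = 5.29e-07 over all named probe sets), more than Hoxa9. Meis1 was not called on its main probe set in CMP (1.24), while another Meis1 probe set rose by 1.97 ± 0.26 (adjusted p = 0.00519 over all named probe sets). Among MLL-fusion target genes Mecom rose while Pbx3, a cofactor of Hox proteins (−1.25 ± 0.19, adjusted p = 0.00784, with −0.35 and no call on another probe set), and Eya1 (−1.03 ± 0.16, adjusted p = 0.00706) fell. That list was not called (mean 0.13, median −0.003, adjusted p = 0.792), with 3 members higher and 4 lower adjusted over the list alone.

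Stem cell genes rose as a list in CMP (mean 0.40, median 0.11, adjusted p = 0.000235), with adjusted p = 0.283 with an estimated correlation. Mecom was the called member of 22, and 6 were higher and 1 lower adjusted over the list alone. Neutrophil and primary granule genes fell (mean −0.68, adjusted p = 0.000726), with adjusted p = 0.426 with an estimated correlation. None of 17 was called over all genes or adjusted over the list alone, and the calprotectin genes S100a8 (−2.47 ± 0.97) and S100a9 (−2.40 ± 0.91) had the smallest p. The neutrophil list no longer passed without wild type replicate 2 (−0.48) or 5 (−0.48) or Mll-AF9 replicate 4 (−0.43). MHC class II genes fell (mean −0.48, adjusted p = 0.00138), with adjusted p = 0.276 with an estimated correlation. H2-Ab1 was the called member of 6 (−1.20 ± 0.17, adjusted p = 0.00345, with −0.31 and no call on another probe set), with 2 lower adjusted over the list alone. Csf1r, the receptor of macrophage colony-stimulating factor, fell by 1.25 ± 0.19 (adjusted p = 0.00745), while the monocyte list was not called (mean −0.12, adjusted p = 0.218, 1 of 15 lower).

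Markers of cells that a CMP sort could carry over were tested as lists. Stroma and endothelium genes fell (mean −0.36, median −0.06, adjusted p = 0.0117), with adjusted p = 0.283 with an estimated correlation, 0 of 11 called over all genes and 2 lower adjusted over the list alone. Their mean level was 5.24 in wild type replicate 5 and 4.35 to 4.43 in the other wild-type replicates, and the list no longer passed without that replicate (−0.19) or Mll-AF9 replicate 4 (−0.32). Fcer1a, the IgE receptor chain of mast cells and basophils, rose from below background by 1.54 ± 0.26 (adjusted p = 0.0143), at least 1.17-fold. Granzyme B, Gzmb, rose by 1.03 ± 0.19 (adjusted p = 0.025). The mast cell and basophil list itself was not called (mean 0.27, median −0.01, adjusted p = 0.135, 2 of 8 higher, 3 adjusted over the list alone). Using the second run alone gave 26 higher and 20 lower genes, and every run with the replicate as a random effect gave 79 and 86. Without Mll-AF9 CMP replicate 3 the lower genes numbered 63. With the Y-linked covariate 28 of the 77 genes were called the same way.

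**Figure D3:**
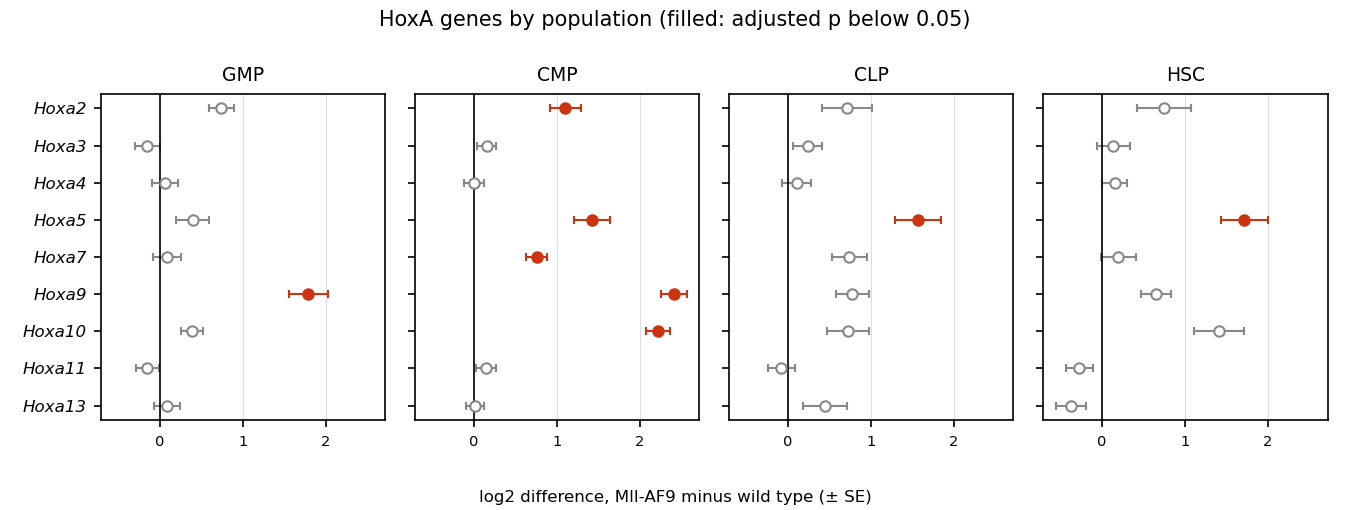
Difference between Mll-AF9 and wild type (x axis, log2, ± SE) of the 9 measured HoxA genes in each population, filled where the adjusted p lay below 0.05. On the chosen probe sets CMP has 5 filled genes, led by Hoxa9 at 2.41, and GMP, CLP and HSC have 1 each. A second Hoxa5 probe set, not drawn, rose by 2.88 in CMP and 2.31 in GMP.

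In CLP, Trgv4, a variable segment of the T cell receptor gamma locus, went from 4.56 ± 0.97 (SD, n = 8) to 8.98 ± 1.16 (SD, n = 7), a difference of 4.42 ± 0.47 (adjusted p = 7.7e-05). Granzyme A, Gzma, rose by 3.46 ± 0.33 (adjusted p = 3.25e-05), the T-lineage factor Bcl11b by 2.91 ± 0.57 (adjusted p = 0.0246), Trbv1 by 2.42 ± 0.49 and the thymocyte gene Themis by 2.19 ± 0.38. Vpreb1, the surrogate light chain of pre-B cells, fell by 3.55 ± 0.51 (adjusted p = 0.002), the B-lineage linker Blnk by 2.77 ± 0.43 (adjusted p = 0.00317) and Cnn3 by 1.79 ± 0.23 (adjusted p = 0.00075). Skida1 rose by 3.88 ± 0.44 (adjusted p = 0.000158), and Bcas1 (2.90), Bpifc (2.83) and Lypd6b (2.28) rose, while Pbx3 (−3.10), Hmga2 (−2.69), Klhl4 (at least 1.80-fold), Ptger3 (−2.47), Emp1 (−2.14) and Slc35d3 (−2.00) fell. The call of Trbv1 was lost in 17 of 27 alternatives, and other probe sets of Trbv1 (0.20) and Pbx3 (−0.78) were not called.

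limma called 37 genes higher and 26 lower in CLP, 33 and 21 of them with a fitted difference over 2-fold. Wild-type means lay below background for Skida1 (at least 6.96-fold), Gzma (at least 8.96-fold), Themis (at least 2.97-fold) and Lypd6b (at least 3.41-fold). Mll-AF9 means did so for Pbx3 (at least 4.94-fold), Klhl4 and the Y-linked Eif2s3y (at least 8.01-fold) and Kdm5d (at least 2.63-fold). Xist (5.73 ± 1.18), Eif2s3y (−4.99 ± 1.01) and Kdm5d (−3.46 ± 0.70) were among the called genes, with the calls ended in 19 of 28, 18 of 27 and 17 of 27 alternatives. The 3' minus 5' control difference was 4.18 ± 0.53 (SD, n = 7) in Mll-AF9 CLP and 3.69 ± 0.21 (SD, n = 8) in wild-type CLP. That is a difference of 0.49 (2-sided exact permutation p = 0.0256, adjusted p = 0.103 over the 4 populations). With the 3' minus 5' difference as a covariate 19 of the 63 genes were called the same way. With the Y-linked covariate only Gzma was called (3.55 ± 0.51, adjusted p = 0.0327), Trgv4 having a difference of 3.82 ± 0.72 (adjusted p = 0.199) and Vpreb1 one of −2.09 ± 0.67 (adjusted p = 0.89).

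Lymphoid progenitor genes fell as a list in CLP (mean −0.83, adjusted p = 4.62e-13) and did so with an estimated correlation (adjusted p = 0.0229). Of 19 members Vpreb1, Blnk and Cnn3 fell, and 8 were lower adjusted over the list alone. Il7r had a difference of −0.06, but this mean covers unlike replicates. It lay at 10.17 to 10.91 in Mll-AF9 replicates 1 to 4 and 7.70 to 8.50 in replicates 5 to 7, against 7.16 to 10.94 in wild type. The lymphoid marker Dntt went from 12.30 ± 0.25 (SD, n = 8) to 11.67 ± 0.53 (SD, n = 7) without a call. Mature T and NK cell genes, fixed as possible carry-over in the sort, rose (mean 0.66, median 0.24, adjusted p = 3.68e-05), with adjusted p = 0.137 with an estimated correlation. Gzma was the called member of 14, and 3 were higher adjusted over the list alone. The T cell receptor components Cd3d, Cd3e and Cd3g had differences of 0.09 ± 0.25, 0.29 ± 0.19 and 0.66 ± 0.20 with means of 4.84 or below in Mll-AF9, near background. The mature B cell list was not called (mean −0.09, adjusted p = 0.594).

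HoxA genes rose as a list in CLP (mean 0.58, adjusted p = 3.68e-05, and adjusted p = 0.0229 with an estimated correlation). Hoxa5 was the called member (1.57 ± 0.28, adjusted p = 0.0113), and 4 were higher adjusted over the list alone. A second Hoxa5 probe set rose by 1.83 ± 0.27 (adjusted p = 0.00305 over all named probe sets). MLL-fusion target genes fell (mean −0.35, adjusted p = 0.0128), with adjusted p = 0.137 with an estimated correlation. Pbx3 and Tcf4 (−0.75 ± 0.16, adjusted p = 0.0437, lost in 16 of 28 alternatives) fell and Mecom (1.63 ± 0.29, adjusted p = 0.0114) rose, with 1 higher and 4 lower of 16 adjusted over the list alone. Cell cycle genes fell (mean −0.27, adjusted p = 2.07e-07), with adjusted p = 0.137 with an estimated correlation. The mitotic kinesin Kif11 was the called member of 25 (−0.92 ± 0.18, adjusted p = 0.0283), and 3 were lower adjusted over the list alone. Immediate-early and heat-shock genes fell (mean −0.67, adjusted p = 5.82e-08), with adjusted p = 0.201 with an estimated correlation and 0 of 18 called, as with Jun (−1.12 ± 0.40). MYC and ribosome biogenesis genes fell (mean −0.14, adjusted p = 0.00428), with adjusted p = 0.338 with an estimated correlation and 0 of 18 called, and no longer passed without wild type replicate 3 (−0.09).

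The neutrophil list and the mast cell and basophil list passed in CLP with the preset correlation only. Neutrophil genes rose (mean 0.82, median 0.31, adjusted p = 0.0297), with adjusted p = 0.541 with an estimated correlation and 0 of 17 called, as with Camp (2.46 ± 0.92) and Ngp (2.62 ± 1.07). Mast cell and basophil genes fell (mean −0.68, adjusted p = 0.0178), with adjusted p = 0.486 with an estimated correlation and 0 of 8 called, as with Mcpt8 (−1.71 ± 0.69). Neutrophil genes no longer passed without wild type replicate 1 (0.71), 3 (0.68) or 5 (0.61) or Mll-AF9 replicate 1 (0.70), 2 (0.55) or 7 (0.86). Mast cell genes had mean levels of 8.62 and 9.58 in wild type replicates 6 and 7 and 6.33 to 7.24 in the others, and no longer passed without wild type replicate 6 (−0.48) or 7 (−0.34) or Mll-AF9 replicate 1 (−0.50), 5 (−0.52) or 6 (−0.57). Both lists and the stress and MYC lists had 0 members called adjusted over the list alone. Fhl1, on the stem cell list, fell by 1.92 ± 0.20 (adjusted p = 5.99e-05), while that list was not called (mean −0.02, median 0.06, adjusted p = 0.327). Without wild type CLP replicate 2, 24 genes were higher and 12 lower, and the lower genes numbered 17 without wild type replicate 1 and 15 without Mll-AF9 replicate 7.

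**Figure D4:**
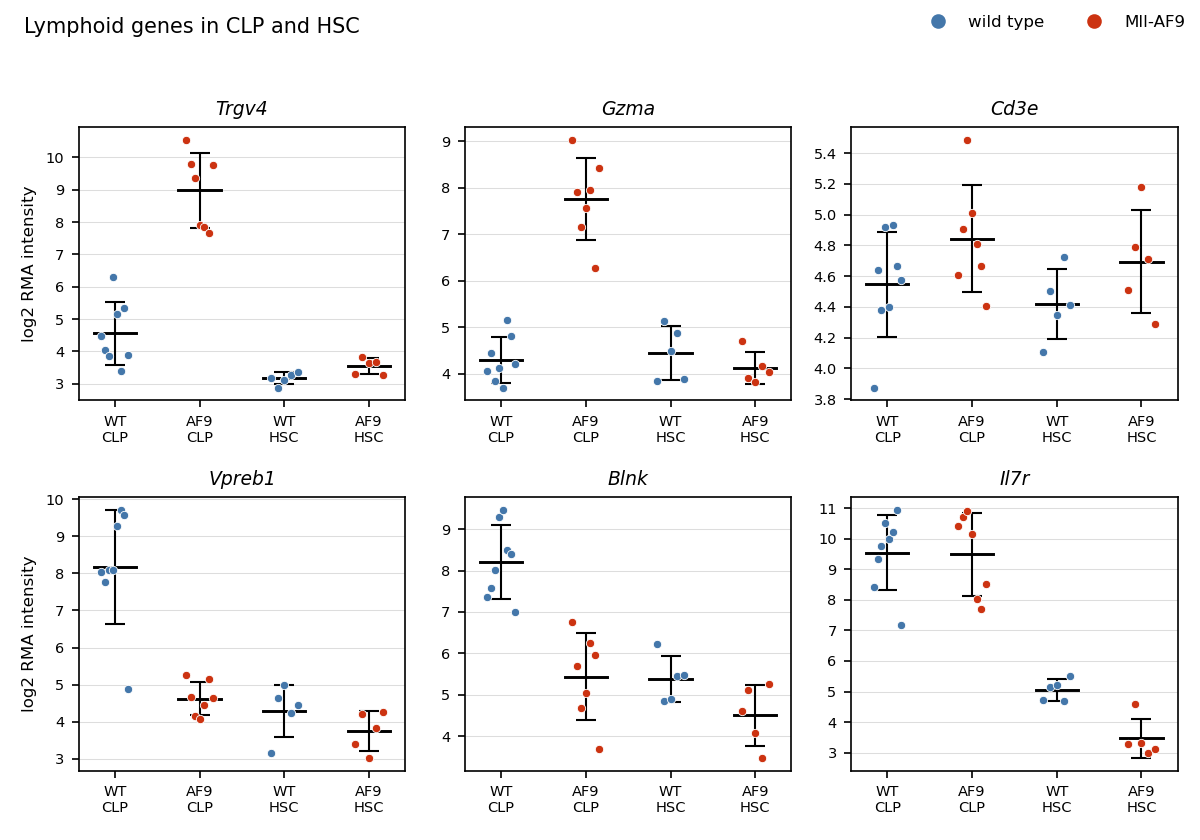
Level of the T and NK cell genes Trgv4, Gzma and Cd3e and of the lymphoid progenitor genes Vpreb1, Blnk and Il7r (y axis, log2 RMA intensity) in CLP and HSC, 1 point per replicate, with the group mean (bar) and SD (error bar), wild type in blue and Mll-AF9 (AF9) in red. In CLP, Trgv4 rose by 4.42 and Vpreb1 fell by 3.55, while Cd3e differed by 0.29 without a call.

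In HSC, 4 genes were higher and 6 lower, all with a fitted difference over 2-fold. Skida1 rose by 2.72 ± 0.34 (adjusted p = 0.00772), Il18r1 by 2.65 ± 0.36 (adjusted p = 0.0122), the clone gene A930004D18Rik, named outside the rule after its value was seen, by 2.26, and Hoxa5 by 1.72 ± 0.28 (adjusted p = 0.0438). Klhl4 fell from 5.91 ± 0.67 (SD, n = 5) to below background, a difference of −3.31 ± 0.33 (adjusted p = 0.000881) and at least 2.73-fold. Il17re (−2.51), Hmga2 (−2.02), the transporter Slco3a1 (−1.79), the actin-binding cortactin gene Cttn (−1.64) and Zfp658 (−1.30, below background in Mll-AF9 and at least 1.10-fold) also fell. The call of Il17re was lost in 7 of 22 alternatives, with −0.63 on another probe set. Skida1 lay below background in wild-type HSC (at least 3.26-fold), and the call of Hoxa5 was lost in 15 of 22 alternatives. Mecom, already at 8.77 ± 0.79 (SD, n = 5) in wild-type HSC, had a difference of 1.62 ± 0.31 that was not called (adjusted p = 0.087), and Meis1 one of 0.90 ± 0.26 (adjusted p = 0.442).

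As lists in HSC, HoxA genes rose (mean 0.49, adjusted p = 0.0025), with adjusted p = 0.23 with an estimated correlation and 3 of 9 higher adjusted over the list alone. Lymphoid progenitor genes fell (mean −0.57, adjusted p = 9.84e-07), with adjusted p = 0.0607 with an estimated correlation. None of 19 was called over all genes and 5 were lower adjusted over the list alone, and Il7r had a difference of −1.59 ± 0.28 (adjusted p = 0.0636). MHC class II genes fell (mean −0.57, adjusted p = 6.36e-05), with adjusted p = 0.125 with an estimated correlation, 0 of 6 called over all genes and 3 adjusted over the list alone. Stem cell genes rose (mean 0.32, adjusted p = 0.00134), with adjusted p = 0.343 with an estimated correlation, 0 of 22 called over all genes and 3 higher adjusted over the list alone. Neutrophil genes (mean −0.51, adjusted p = 0.00501), mast cell genes (mean −0.65, adjusted p = 0.0146) and cell cycle genes (mean −0.23, adjusted p = 0.0242) fell, with adjusted p = 0.441, 0.429 and 0.662 with an estimated correlation. None of their members was called over all genes or adjusted over the list alone. Neutrophil genes no longer passed without wild type replicate 5 (−0.40) or Mll-AF9 replicate 3 (−0.24) or 4 (−0.28), and stood at −0.83 without Mll-AF9 replicate 1. Mast cell genes no longer passed without wild type replicate 2 (−0.42) or 5 (−0.53) or Mll-AF9 replicate 3 (−0.37) or 4 (−0.45). Cell cycle genes no longer passed without wild type replicate 3 (−0.09) or 5 (−0.08) or Mll-AF9 replicate 2 (−0.17), 3 (−0.15) or 4 (−0.12), and stood at −0.43 without wild type replicate 1 and −0.36 without Mll-AF9 replicate 1 or 5. With the Y-linked covariate 3 of the 10 genes were called the same way. Higher and lower genes numbered 2 and 1 without wild type HSC replicate 2, and 1 and 1 without Mll-AF9 replicate 3 or 4, and 2 genes were lower without wild type replicate 1.

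The lists not named with a call did not pass in any population. Mean differences in GMP, CMP, CLP and HSC were −0.05, 0.07, −0.14 and −0.09 for HoxB, 0.07, 0.07, −0.09 and −0.34 for mature B cell genes, and 0.03, 0.11, 0.18 and 0.01 for interferon response genes. They were 0.10, 0.06, −0.09 and 0.15 for p53 response genes and 0.14, 0.15, 0.05 and 0.13 for CDK inhibitors. The medians had the other sign for HoxB in HSC, for p53 response in CLP, and for mature B cell genes in CLP and HSC. The smallest adjusted p among these was 0.076, for interferon response in CMP. Hoxb3 had the largest difference of the HoxB genes in CLP, −1.27 ± 0.32 (adjusted p = 0.116).

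Several genes changed in more than 1 population, and no libraries are shared between the comparisons. Whether the same mice supplied several populations is not given in the sources used here. In wild-type GMP and CMP alike, replicates 1 to 3 had low Xist and replicates 4 and 5 high Xist, and the sex imbalance is shared by all comparisons, which the numbers expected from independent lists leave out. Skida1 was higher in all 4, where independent lists would share 3.28e-08 genes, and no gene was lower in all 4. Genes higher in 3 populations numbered 7, including Mecom, Bpifc and Selp in GMP, CMP and CLP, and Hoxa5 and Il18r1 in CMP, CLP and HSC. Genes lower in 3 numbered 4: Ptger3 in GMP, CMP and CLP, and Hmga2 (in CMP by a call lost in 17 of 24 alternatives), Klhl4 and Cttn in CMP, CLP and HSC. GMP and CMP shared 12 higher genes against 0.0733 expected from independent lists, and CMP and CLP shared 12 higher and 8 lower genes against 0.0875 and 0.0486. Prdm16, a stem cell regulator related to Mecom, was called in opposite directions, with 1.34 ± 0.17 in GMP, 0.91 ± 0.12 in CMP and −1.58 ± 0.31 in CLP. A second Hoxa5 probe set rose in GMP as well (2.31 ± 0.21, adjusted p = 0.000295 over all named probe sets), where the chosen one had a difference of 0.40 ± 0.20. In HSC the second probe set had a difference of 1.36 ± 0.38 and was not called (adjusted p = 0.515 over all named probe sets, 0.0897 for the chosen one). With the Y-linked covariate no gene was called higher in all 4, Skida1 having a difference of 4.31 ± 0.68 in CLP (adjusted p = 0.0515). Without wild type HSC replicate 1 or Mll-AF9 HSC replicate 2, 2 genes were higher in all 4, and without wild type GMP replicate 1, 2 were lower in all 4.

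The test of the difference between populations asked whether genotype effects were unequal, and pairs with CMP depend on whether CMP arrays were processed like the others. Between GMP and CLP it called 12 genes, led by Trgv4 (GMP minus CLP −4.58 ± 0.55), Vpreb1 (4.03 ± 0.62), Gzma (−3.33 ± 0.42), Prdm16 (2.92 ± 0.41) and Blnk (2.67 ± 0.54). Between CMP and CLP it called 12, led by Trgv4 (−3.82 ± 0.55), Gzma (−3.56 ± 0.42), Vpreb1 (3.37 ± 0.62), Blnk (2.58 ± 0.54) and Fgf13 (2.56 ± 0.44), and among them Mecom (2.28 ± 0.44, adjusted p = 0.00951) and Hoxa9 (1.63 ± 0.31, adjusted p = 0.00818). Between CLP and HSC it called 26, led by Trgv4 (4.04 ± 0.53), Gzma (3.78 ± 0.40), Vpreb1 (−2.99 ± 0.60), Ccl5, a chemokine of T and NK cells (2.61 ± 0.47), and Trbv1 (2.57 ± 0.56). Between GMP and HSC it called 8, led by Ighm, the immunoglobulin mu heavy chain (2.71 ± 0.55), Tmem178 (2.50 ± 0.42), Prdm16 (2.24 ± 0.45), Tmem98 (−1.95 ± 0.41) and Kif23 (1.88 ± 0.39). The differences of Ighm, Prdm16, Tmem98 and Kif23 between GMP and HSC were lost in 16, 14, 19 and 20 of 26 alternatives. Vpreb1 had wild-type means of 8.17 in CLP but 4.56 in GMP, 4.23 in CMP and 4.30 in HSC, near or below background. Blnk lay at 4.13 to 4.60 in wild-type GMP and 3.86 to 4.70 in wild-type CMP replicates. Neither could fall much there, so these differences do not separate an unequal effect from an unequal starting level. Mecom likewise started from 4.30 in wild-type CMP and 8.42 in wild-type CLP. limma called 0 genes between GMP and CMP (335 at an unadjusted p below 0.05, and 12 called with those 4 groups alone). It called 0 between CMP and HSC (530 at an unadjusted p below 0.05, and 4 called with those groups alone). Both numbers lie below the 910 of 18193 genes that chance gives at that p. The model shares 1 spread over 8 groups, while the median SE of the genotype comparison was 0.124 in CMP and 0.227 in HSC. That spread can be too large for CMP, so 0 calls do not show equal effects. In simulated data that held changed genes, this test made 12.2 false calls per simulation for GMP and CLP, 4.8 for CMP and CLP, 50.6 for CLP and HSC and 15.4 for GMP and HSC. With no change simulated it called at most 5, 1, 17 and 8 genes. The fit with 4 groups alone called 5 genes for GMP and CLP, 7 for CMP and CLP, 5 for CLP and HSC and 5 for GMP and HSC. The counts also changed with single replicates. For GMP and CLP the count was 6 without wild type GMP replicate 1 or 4, 7 without wild type CLP replicate 4 or Mll-AF9 GMP replicate 4, 19, 20 and 29 without wild type CLP replicates 6, 7 and 8, and 22 and 23 without Mll-AF9 CLP replicates 3 and 4. For CLP and HSC it was 14 and 16 without wild type HSC replicates 1 and 2, and 11 and 57 without Mll-AF9 HSC replicates 3 and 5. For GMP and HSC it was 25 without Mll-AF9 HSC replicate 5 and 1 to 5 without any 1 of the GMP replicates, wild type HSC replicates 1 and 2, or Mll-AF9 HSC replicates 1, 3 and 4. For GMP and CMP it was 1 without Mll-AF9 GMP replicate 2, and for CMP and HSC 1 and 3 without wild type HSC replicates 4 and 5.

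Wild-type signatures asked whether Mll-AF9 progenitors carry more of the stem cell's expression. Genes higher in wild-type HSC had a mean difference of 0.04 in Mll-AF9 GMP (adjusted p = 0.23) and 0.07 in CMP (adjusted p = 0.143), neither called. Mecom, Hoxa9 and Prdm16 were higher in both, while Basp1 and Zfp521 were lower in GMP and 4 members, Eya1, Klhl4 and Cttn among them, lower in CMP. The surface markers of the HSC gate are not given in the sources used here, so how pure a stem cell signature this is stays open. The signatures tested in GMP and HSC were taken against CMP, whose arrays may have been processed apart. Stem cell genes tested in GMP were chosen against CMP, and those tested in CMP against GMP. They need not be low in the tested wild-type population, so these means do not settle whether stem cell expression was gained. In CLP the stem cell genes, taken against GMP, were lower by a mean of −0.14 (adjusted p = 0.000193, and adjusted p = 0.515 with an estimated correlation). Wild-type CLP and HSC themselves differed in only 8 called genes, so this test does not measure a gain or loss of what sets HSC apart from CLP. Genes higher in wild-type GMP were lower in Mll-AF9 CMP by a mean of −0.12 (adjusted p = 6.08e-05) and in HSC by −0.23 (adjusted p = 3.83e-05), both with adjusted p = 0.515 with an estimated correlation. In CLP their mean difference was 0.01 (adjusted p = 0.105), and it was negative without wild type replicate 4, 5 or 8 or Mll-AF9 replicate 2, 4 or 7. The stem cell genes passed in GMP without wild type replicate 1 (0.08) and in CMP without wild type replicate 2 (0.10) or Mll-AF9 replicate 1 (0.10). The GMP genes no longer passed in CMP without Mll-AF9 replicate 3 (−0.07), nor in HSC without wild type replicate 5 (−0.10).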

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

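The tests of sex mix, T cell carry-over and RNA quality, and the simulation with no change, were chosen only after the result was seen.

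The genotype effect differed between populations by its own test. Vpreb1 and Blnk lay near or below background in wild-type GMP and CMP and could hardly fall there. Their differences from CLP therefore do not show an unequal effect apart from the starting level. Between GMP and CLP 12 genes differed, led by Trgv4 (−4.58), Vpreb1 (4.03), Gzma (−3.33), Prdm16 (2.92) and Blnk (2.67). Between CMP and CLP 12 did, led by Trgv4 (−3.82), Gzma (−3.56), Vpreb1 (3.37), Blnk (2.58) and Fgf13 (2.56). Between CLP and HSC 26 did, led by Trgv4 (4.04), Gzma (3.78), Vpreb1 (−2.99), Ccl5 (2.61) and Trbv1 (2.57), and between GMP and HSC 8, led by Ighm (2.71), Tmem178 (2.50), Prdm16 (2.24), Tmem98 (−1.95) and Kif23 (1.88). Of 100 splits of the replicates, the real one included, as many genes came from 1 for GMP and CLP (highest other 8), 1 for CMP and CLP (7), 2 for GMP and HSC (9) and 3 for CLP and HSC (138). With no change simulated, 1 of 20 simulations called as many for GMP and HSC, and none for the other 3 pairs. These simulations drew each gene independently and so lack the correlation between genes of real samples, and they cannot exclude chance. A split with 138 points to structure among the CLP and HSC samples. Chance is left open for CLP and HSC and for GMP and HSC. For GMP and CLP, and for CMP and CLP, no other split reached the count. False calls in simulations with changed genes were many, at 50.6 each for CLP and HSC, so single genes of that pair whose call is lost often, such as Trbv1 (15 of 31 alternatives), are open to doubt, while Trgv4 and Gzma were called in all 31. For GMP and CMP, and for CMP and HSC, the count was 0, which all 100 splits reach by construction (highest other 0 and 3), so the splits say nothing there.

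In Mll-AF9 CLP, the B-lineage genes Vpreb1 (−3.55) and Blnk (−2.77) fell and the T-lineage genes Trgv4 (4.42) and Bcl11b (2.91) rose. Mature T cells carried over in the sort would bring Cd3 transcripts, but the median difference of Cd3d, Cd3e and Cd3g was 0.294, and none reached 1. Cd3d and Cd3g lay below background in both genotypes. The check covers mature T cells only. The list fixed for carry-over also held NK cell genes, and all 14 of its members had a positive difference, with Gzma called. Carry-over of NK cells was not tested and is left open. The 3' minus 5' difference was larger by 0.49 in Mll-AF9 (adjusted p = 0.103 over the 4 populations by exact permutation), and with it as a covariate the called genes kept a median of 0.954 of their difference (1.69 before, 1.63 after), while the SE grew from 0.300 to 0.362 and 19 of 63 calls stayed. A change in which cells fall within the CLP gate, or in the cells themselves, may underlie the pattern, and neither was tested here.

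Genotype and sex overlap, since all 20 Mll-AF9 replicates had female levels of Xist and wild-type groups were mixed. With the Y-linked level as a covariate the called autosomal genes kept a median of 0.981 of their difference in GMP, 0.998 in CMP, 0.940 in CLP and 1.00 in HSC, all with the same sign, which argues against sex mix as the whole cause. Most calls ended all the same (11 of 49 stayed in GMP, 28 of 77 in CMP, 1 of 63 in CLP and 3 of 10 in HSC), while the median SE went from 0.295 to 0.460 in CLP (median difference 1.63 to 1.54) and from 0.304 to 0.333 in HSC. The lower quartile of the share kept was 0.746 in CLP, and for single genes there, such as Vpreb1 (−3.55 to −2.09) and Hoxa5 (1.57 to 0.97), a part played by sex could not be excluded.

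Hmga2 was lower in CMP (a call lost in 17 of 24 alternatives), CLP and HSC, and Selp higher in GMP, CMP and CLP. Genes kept from the strain of the targeted cells beside Kmt2a would lie near it, but 0% of the 200 nearest tested genes were called (1.71 expected, Fisher p = 0.423), and neither gene lies among them. Older Mll-AF9 mice would raise genes known from old stem cells, and their mean difference in HSC was 0.126 (exact permutation p = 0.325), and in CMP 0.22 (exact permutation p = 0.0238, adjusted p = 0.0952 over the 4 populations). Age cannot be told apart from genotype here, since the labels give no ages and the list mean lay above 0 without passing. An effect of the fusion itself was not tested apart from these.

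Counts of genes called by genotype exceeded those of other splits of the replicates. Of 100 splits, 1 gave as many in GMP (49, highest other 4), CMP (77, highest other 12), CLP (63, highest other 56) and HSC (10, highest other 1), and 1 gave as many genes higher in all 4 populations (1, highest other 0). The CLP split with 56 set wild type replicates 4, 6 and 7 with Mll-AF9 replicates 1 to 4 against the rest, a structure within CLP apart from genotype. Il7r lay at 10.17 to 10.94 in that set and at 7.16 to 9.99 in the rest. Called lists numbered as many in 3 of 100 splits in GMP (5, highest other 6), 25 in CMP (5, highest other 11), 6 in CLP (9, highest other 10) and 12 in HSC (7, highest other 12). The median over the other splits was 1 list in GMP, 2 in CMP, 4 in CLP and 3 in HSC. Some lists were thus called when replicates were grouped otherwise than by genotype. These counts rest on the preset correlation and test the number of lists, not any single list. None of the lists called in GMP passed with an estimated correlation. HoxA genes in CMP and CLP and lymphoid progenitor genes in CLP did. By fry, HoxA passed in each population (adjusted p = 0.0122 in GMP, 0.000385 in CMP, 0.00278 in CLP and 0.0378 in HSC). MLL-fusion target genes passed by fry in GMP (0.0218), stem cell genes in CMP (0.0394), and T and NK cell genes in CMP (0.0394) and CLP (0.0203). Lymphoid progenitor genes did in CLP (0.00792) and HSC (0.0378), and MHC class II genes in HSC (0.0378). The other lists did not pass by fry. Signature means were as large in 55 splits for stem cell genes in GMP (0.04, highest other 0.129), 18 in CMP (0.07, highest other 0.128) and 45 in CLP (0.137 in size, highest other 0.333). For GMP genes 18 splits did so in CMP (0.118 in size, highest other 0.174), 97 in CLP (0.01, highest other 0.268) and 11 in HSC (0.228 in size, highest other 0.271), so chance was not excluded for any signature.

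Single replicates stood far from the others of their group for 7 of 146 gene and group pairs, where chance gives 7.3, and no replicate did so more than 1 time. The gap over the range was 0.834 for Tal1 in Mll-AF9 GMP replicate 4, 0.916 for Bpifc in Mll-AF9 CMP replicate 3, 0.764 for Bpifc in wild type CLP replicate 7 and 0.595 for Vpreb1 in wild type CLP replicate 8. It was 0.723 for Skida1 in wild type HSC replicate 1, 0.791 for Hoxa5 in wild type HSC replicate 5 and 0.895 for Il17re in Mll-AF9 HSC replicate 5. Among 10092 probe sets outside the gene table, 18 were called in GMP (17 higher), 13 in CMP (11 higher), 14 in CLP (3 higher) and 1 in HSC (higher).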

How the results depend on the processing

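The Y-linked covariate and the fit without replicates with a high 3' minus 5' difference were chosen only after the result was seen; the cause of a change was not tested unless stated. Leaving aside single replicates, named genes kept the side of the threshold in 3434 cases, were weaker in 216 and stronger in 50, and lists did so in 784, 62 and 22. In 51 of these cases a gene called in neither fit changed sign, and in 35 a list did. Without 1 replicate, genes were the same in 2911, weaker in 218 and stronger in 12, and no called gene turned, while lists were the same in 760, weaker in 34 and stronger in 23. Of those counted as the same, 71 for genes and 33 for lists had another sign without a call in either fit. Genes named for a difference between populations were the same in 107 and weaker in 21, and without 1 replicate in 369 and 91. With the Y-linked covariate Xist in CLP turned to −0.11, Eif2s3y in CLP, from which the covariate is built, to 0.0151, and the interferon list in HSC to −0.31 (adjusted p = 0.0137). Whether replicate numbers pair the samples is open. Between genotypes of a population, the best match had its own number for 0 of 4 in GMP, 2 of 4 in CMP, 1 of 7 in CLP and 0 of 5 in HSC. Pairing across populations was not tested. Arrays have no depth, and 55.5% to 63.2% of the genes of a replicate lay above background.

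Counts are given as higher and lower genes. One model over 8 groups gave 17 and 9 in GMP, 8 and 1 in CMP, 158 and 113 in CLP, 29 and 49 in HSC, and 2 and 1 in all 4. Array weights gave 134 and 84 in GMP, 55 lower in CMP, 113 and 87 in CLP, 15 and 24 in HSC, 3 and 2 in all 4, and differences between populations of 13 for GMP and CMP, 128 for GMP and CLP, 19 for GMP and HSC, 97 for CMP and CLP, 16 for CMP and HSC and 17 for CLP and HSC. Genes at or above the median level, with fewer genes tested, gave 19 higher in GMP, 25 and 19 in CMP, 19 and 16 in CLP, 14 lower in HSC, and 4 for GMP and CLP, 5 for GMP and HSC, 6 for CMP and CLP, 1 for CMP and HSC and 1 for CLP and HSC. Every probe set tested gave 61 higher in GMP, 52 lower in CLP, and 2 and 1 in HSC. The replicate number as a block gave 15 and 2 in GMP, 11 lower in HSC, and 4 for GMP and HSC, 1 for CMP and HSC and 17 for CLP and HSC. The Y-linked covariate gave 11 and 10 in GMP, 26 and 9 in CMP, 1 and 0 in CLP, 1 lower in HSC and 0 higher in all 4. Without replicates with a high 3' minus 5' difference there were 92 and 51 in GMP, 23 and 13 in CLP and 1 lower in all 4, and with that difference as a covariate 12 and 7 in CLP and 8 higher in HSC. A prior without trend gave 3 lower in HSC and 4 for GMP and HSC, genes above background 11 lower in HSC, and median centring 17 for CLP and HSC. The second run alone gave 26 and 20 in CMP, and every run 79 and 86. With 4 groups alone the counts were 12 for GMP and CMP, 5 for GMP and CLP, 5 for GMP and HSC, 7 for CMP and CLP, 4 for CMP and HSC and 5 for CLP and HSC. The stem cell signature in CMP passed with 100 genes (0.18). With an estimated correlation those in CLP (−0.14), and the GMP signature in CMP (−0.12) and HSC (−0.23), no longer passed, and against the other wild-type population the GMP signature in HSC (−0.0553) did not. The stem cell signature against that population held 0 genes and gave no value in GMP and CMP.

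Without 1 replicate, higher and lower counts ranged from 16 to 92 and 4 to 51 in GMP, 33 to 55 and 24 to 63 in CMP, 24 to 42 and 12 to 29 in CLP, 1 to 5 and 1 to 9 in HSC, and 1 to 2 and 0 to 2 in all 4. Differences between populations ranged from 0 to 1 for GMP and CMP, 6 to 29 for GMP and CLP, 1 to 25 for GMP and HSC, 8 to 17 for CMP and CLP, 0 to 3 for CMP and HSC and 11 to 57 for CLP and HSC. Stem cell signature means ranged from 0.0114 to 0.0817 in GMP, 0.0451 to 0.102 in CMP and −0.225 to −0.0777 in CLP, and GMP signature means from −0.16 to −0.0680 in CMP, −0.0588 to 0.0674 in CLP and −0.276 to −0.0980 in HSC. Without wild type CLP replicate 1, whose source name conflicts with its title, CLP had 42 calls, 41 of them among the 63.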

Other observations

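The comparison of populations below was chosen only after the result was seen.

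Between wild-type CLP and HSC limma called 8 genes, all higher in CLP (Il7r, Rag1, Vpreb1, Blnk, Trbv1, Gimap4, Maf and Cmah), whereas the other pairs of wild-type populations differed in 4460 to 8383 genes, and in 6499 and 7134 for the pairs without CMP. Whether CMP arrays were processed like the others is not given in the sources used here, and the counts with CMP depend on it. Il7r had a mean of 9.54 in wild-type CLP and 5.05 in wild-type HSC, while Dntt (12.30 and 11.59), Flt3 (10.05 and 9.86), Mpo (11.79 and 11.51), Mecom (8.42 and 8.77) and Procr, a stem cell marker (8.58 and 8.56), lay close together. Between Mll-AF9 CLP and HSC 60 genes differed, 53 of them higher in CLP, and Il7r was 9.49 and 3.47. Hlf, on the stem cell list, had means of 9.31 in wild-type CLP and 10.07 in wild-type HSC. The surface markers of each gate are not given in the sources used here. How far the HSC samples hold other early progenitors, or the CLP samples hold cells other than lymphoid progenitors, is therefore not known.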
